A study of Rattus norvegicus with 9 samples.

How the data were processed

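RNA of the hippocampus was measured in 9 libraries, 3 per group, from male Sprague-Dawley rats: Ctrl, Model and ChryM. Poly(A) RNA was made into strand-specific (dUTP) libraries, per the labels. Read counts per gene were deposited as whole numbers, and FPKM values were deposited in a second table with a gene length per gene, per the file headers. HISAT2 and DESeq2 are named without a version, per the submitters' processing notes. The counting tool, its strand setting, the genome build and the annotation are not given in the sources used here. The deposited FPKM equalled the deposited count over gene length and library total in 100.0% of values, at a relative tolerance of 1e-09, so both tables hold the same measurement. Gene length was taken from the deposited table, per the file headers, and used in that check and for FPKM of simulated data.

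The count table held 30562 genes, of which 4367 IDs carried no gene name; 544 IDs shared a symbol with another ID and were kept apart. Of 26195 gene names, 23440 were found in a RefSeq gene table of the assembly GRCr8, which was used for overlaps and for neighbours within 5 kb, and which gives no strand. Names not found there were kept as the file gives them. Library totals ran from 631119 to 866048 counts, and 13343 to 14256 genes had at least 1 count. No pair of libraries held identical values.

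Genes were kept with edgeR's filterByExpr, which left 7073, and scaled with TMM factors of 0.9557 to 1.065. One fit with a coefficient per group and no covariate was made on all 9 libraries with edgeR 4.0.16 (glmQLFit, robust) in R 4.3.3, leaving 6 residual degrees of freedom. Model vs Ctrl, ChryM vs Model and ChryM vs Ctrl were tested with glmQLFTest, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors were taken from the fold change and its F statistic, which put them below the counting error of the summed counts in 740, 602 and 490 genes of the 3 comparisons. The larger of the 2 errors is printed, while the p-values are those of the test. Of called genes with counts in both groups, 217 of 879, 122 of 584 and 292 of 1328 had a test error below counting error. The p-values of those calls may be too small. Ratios of few counts have exact binomial 95% intervals. CPM of single genes are TMM-scaled, while sums over lists are CPM of the library total.

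Before the data were examined, 53 gene lists, a panel of 32 genes and the rule for named genes were fixed. The rule takes, among called genes with a symbol, a mean of at least 1 CPM and groups that do not overlap, the 6 with the smallest p and the 6 with the largest fold in each direction for Model vs Ctrl and ChryM vs Model. It takes the 5 with the smallest p in each direction for ChryM vs Ctrl, up to 4 members per list by smallest p, and the 12 opposed genes with the smallest larger p. Of the lists, 36 had at least 5 tested members and were tested with limma 3.58.1's camera on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over those 36. Camera with an estimated correlation was run beside it, and so was fry. The fry calls ask whether the genes of a list move one way, without comparing them with the other genes as camera does. The p of fry for change in either direction was not used for calls. The other 17 lists are given as sums. Opposed changes were set beside 100 simulated data sets with no group difference and the same shared Model libraries.

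The pipeline was tested on simulated data of the observed depth. For folds of 1.25, 1.5, 2 and 4, the edgeR test recovered 4%, 18%, 52% and 96% of planted genes in Model vs Ctrl and 8%, 28%, 72% and 94% in ChryM vs Model. Of 6853 unchanged genes, 4 and 2 were called. A planted covariance of -0.0283 was recovered as -0.0297. A planted list of 20 genes was called by camera in both comparisons, and with an estimated correlation only in ChryM vs Model; none of 50 random lists was called.

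Alternatives fixed before the data were examined were other size factors, library totals, DESeq2 1.42.0, limma-voom, other count filters, a fit of only the groups compared, a spread that is not robust, a replicate block, 1 surrogate variable (sva 3.50.0), a fold minimum, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other list tests, and leaving out each library. Added after the data were seen were a restriction to genes over 5 kb from another gene, the removal of marker genes of other tissues and myelin, and a mean count of at least 30. DESeq2 was run on all 30562 genes, without the count filter of the main fit. Whether the surrogate variable follows a group was not examined, so a call lost with it may reflect that adjustment or a weak call. Raw reads were not analysed here. Some items are withheld for evaluations and are not reported here.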

Results

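RNA was sequenced from the hippocampus of male Sprague-Dawley rats in 3 groups of 3 libraries each: untreated controls (Ctrl), rats given a diabetes and stress protocol (Model), and rats given chrysophanol by oral gavage for 14 consecutive days (ChryM). Chrysophanol is a plant anthraquinone. The diabetes protocol was a high-fat diet for 4 weeks followed by an injection of streptozotocin, a toxin of insulin-producing cells, at 50 mg/kg. It was followed by 5 weeks of unpredictable mild stress. That the ChryM rats were model rats follows from the series title, which names rats with diabetes and depression together; the dose and the meaning of the letter M are not stated in the labels. Total counts per library were 802838, 807513 and 727070 for Ctrl 1 to 3, 660400, 631119 and 772765 for Model 1 to 3, and 816604, 866048 and 767707 for ChryM 1 to 3. Such totals are low for a whole transcriptome: of 30562 genes in the table, 7073 had enough counts to be tested, and the median tested gene had 19 to 27 counts per library. IDs without a gene name held 21.99% to 24.58% of the counts of each library. The strand setting of the counting is not given, and counting on the strand opposite to transcription stays an open hypothesis. Counts under a gene's name below may therefore not all be reads of its mRNA.

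The 3 groups separated on the first 2 principal components, which held 27.5% and 19.3% of the variance. Replicate libraries of a group differed little beyond counting noise. Across the 4220 to 5556 genes with at least 30 summed counts in a pair of libraries, the squared difference between the pair was 1.246 to 2.325 times the counting variance within groups, against 3.33 to 4.92 times between groups. The biological coefficient of variation was 5.50% over all groups. The labels do not tie the libraries to animals, and the p-values below measure only the spread between these libraries, which may be technical. Gene levels are given as CPM (counts scaled to a common library size by the trimmed mean of M-values) with the SD over 3 libraries, and changes as log2 fold changes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. The standard error (SE) beside a fold change is the larger of that from the test and the counting error of the summed counts.

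The first comparison, Model against Ctrl, addresses what the diabetes and stress protocol goes with in hippocampal RNA. The largest change was the near loss of Ttr (ENSRNOG00000016275), which encodes transthyretin, a thyroid hormone carrier made in bulk by the choroid plexus. Ttr stood at 1520 ± 30.9 CPM in Ctrl and 3.14 ± 0.347 CPM in Model. Its summed counts were 3587 and 6, a ratio of Ctrl to Model of 488 with a 95% counting interval of 224 to 1330. The log2 fold change was -8.86 ± 0.59 (adjusted p = 3.86e-110). Other transcripts of choroid plexus and meninges fell with it. Enpp2 (ENSRNOG00000004089), which encodes the secreted lysophospholipase autotaxin, went from 184 ± 10.3 to 32.2 ± 8.02 CPM. Igf2 (ENSRNOG00000020369), a growth factor of the meninges and choroid plexus, went from 112 ± 20.8 to 9.78 ± 1.24 CPM. Their log2 fold changes were -2.48 ± 0.195 (adjusted p = 1.41e-30) and -3.47 ± 0.34 (adjusted p = 4.71e-28).

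Low-count genes with large falls were Clic6 (ENSRNOG00000026870), a chloride channel gene of the choroid plexus, with 51 counts in Ctrl and 2 in Model, and Mfrp (ENSRNOG00000039107), a membrane frizzled-related protein gene, with 59 and 2. The ratios of Ctrl to Model were 20.8 with a 95% counting interval of 5.48 to 177, and 24.1 with an interval of 6.38 to 204. Cdkn1c (ENSRNOG00000059500), which encodes a cyclin-dependent kinase inhibitor, fell from 81 to 8 counts. Intervals of counts cover counting error only. The adult alpha globin gene Hba-a1 (ENSRNOG00000029886) fell from 246 ± 1.29 to 56.0 ± 6.42 CPM, a log2 fold change of -2.14 ± 0.15 (adjusted p = 1.45e-32).

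Myelin transcripts made up the other large fall. Cldn11 (ENSRNOG00000010263), a tight-junction gene of the myelin sheath, fell by 1.75 ± 0.12 on the log2 scale, from 330 ± 38.5 to 98.5 ± 14.3 CPM (adjusted p = 8.01e-30). Mal and Cnp, a myelin proteolipid and a myelin phosphodiesterase, fell by 1.47 and 1.12 on the log2 scale. Of the 14 tested members of the oligodendrocyte and myelin list, 12 fell and 0 rose (13 fell when adjusted over the list alone), with a median log2 fold change of -1.06. As a set the list moved down against the other genes (camera adjusted p = 4.77e-26). Its adjusted p was 0.00252 with an estimated correlation between genes, and it was the only one of the 6 lists called in this comparison to keep its call there.

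Among the genes that rose in Model, Sncg (ENSRNOG00000058006), which encodes gamma-synuclein, rose from 8.82 ± 5.86 to 109 ± 17.8 CPM, a log2 fold change of 3.67 ± 0.34 (adjusted p = 7.05e-30). Necab1 (ENSRNOG00000007256), a neuronal calcium-binding protein gene, rose from 2140 ± 216 to 3850 ± 52.1 CPM, by 0.85 ± 0.07 on the log2 scale (adjusted p = 2.95e-23). The smallest p of a rise belonged to Or2b4 (ENSRNOG00000065474), an olfactory receptor gene, at 1.55 ± 0.09. Cibar2 (0.83), a ciliary protein gene, Alg3 (0.81), a mannosyltransferase gene of protein glycosylation, and Ube3a (0.92), a ubiquitin ligase gene, followed. Ccdc57 (2.52) rose from 8 to 39 counts, and Tmem145 (1.76), Nat8f3 (1.64) and Hsf1 (1.59), the heat shock transcription factor gene, had larger folds at low levels. Nat8f3 and Hsf1 lost their calls with 1 surrogate variable in the fit (adjusted p = 0.135 and 0.399), and Hsf1 also without Model 2 (adjusted p = 0.0790).

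**Figure D1:**
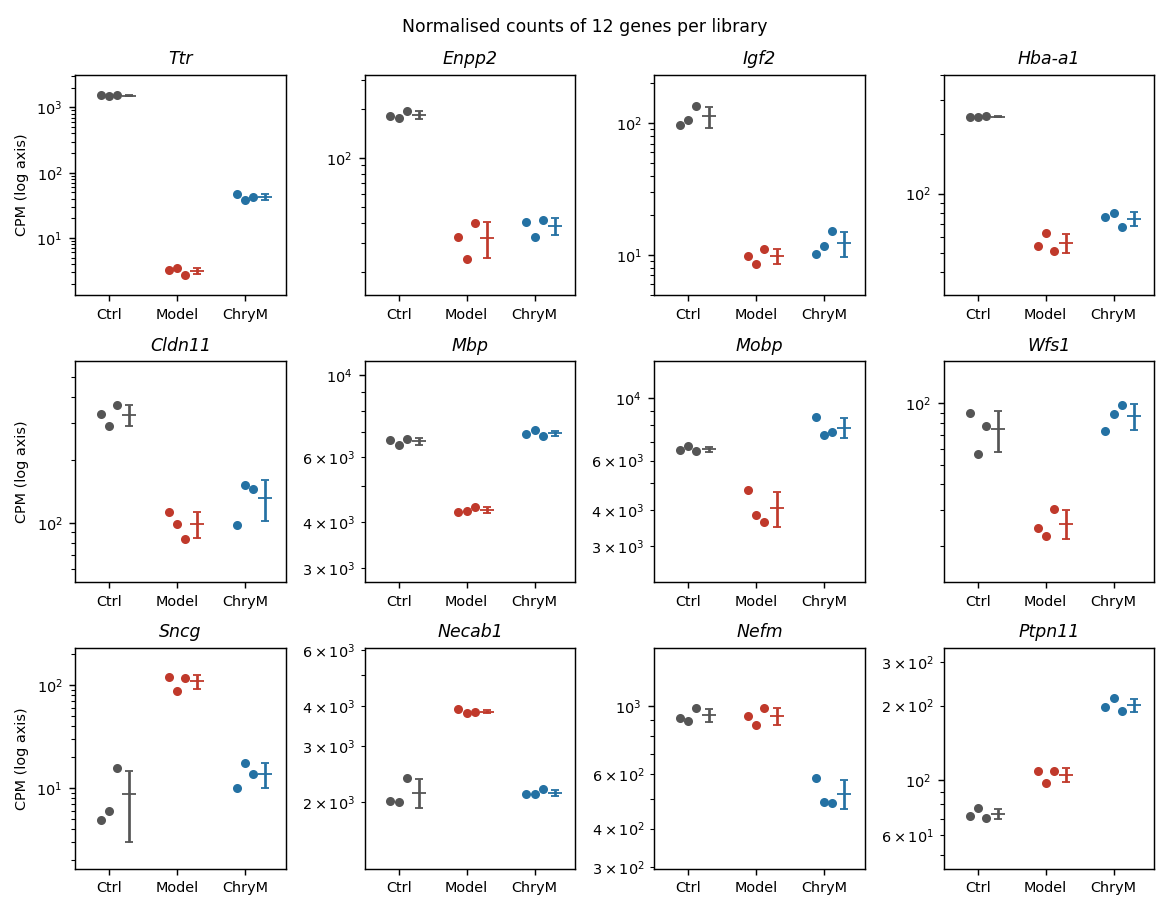
Normalised CPM of 12 genes in the 9 libraries, on log axes; each point is a library, and the bar beside it gives the mean and SD of the group of 3. Ttr, Enpp2, Igf2 and Hba-a1 stayed low in ChryM libraries, while Mbp, Mobp and Wfs1 lay at or above their Ctrl level in them and Sncg and Necab1 near it.

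In all, 879 of 7073 genes changed between Model and Ctrl, 498 higher and 381 lower, and 1665 had an unadjusted p under 0.05. Of those called, 41 rose and 106 fell by at least 2-fold. Changes are relative to the scaling: with library totals alone the median log2 fold change of all genes moved by -0.12, and the split became 276 higher and 655 lower. It was 359 and 81 with DESeq2, 204 and 353 on log2(FPKM + 1), 148 and 124 with 1 surrogate variable, 156 and 284 with a fold of at least 1.5, and 31 and 66 among the 1087 tested genes over 5 kb from another gene.

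Besides myelin, 5 lists were called by camera with the preset correlation. Oligodendrocyte precursor markers had 3 of 7 members lower (5 adjusted over the list alone; Olig1, Sox10 and Cspg4), with a median of -0.74 (adjusted p = 0.0422; adjusted p = 0.174 with an estimated correlation). Insulin and IGF signalling had 3 of 11 lower (4 adjusted over the list alone), among them Igf2 and the binding protein gene Igfbp2 at -2.01 ± 0.25 (list adjusted p = 0.0422; adjusted p = 0.174 with an estimated correlation). Its median was -0.04 against a mean of -0.59. Thyroid hormone response had 2 of 9 lower, Ttr and the myelin basic protein gene Mbp (adjusted over the list alone, 4 lower and 1 higher; adjusted p = 5.02e-05; adjusted p = 0.169 with an estimated correlation). Without genes shared with other lists the thyroid list was not called (adjusted p = 0.862). In that setting 2 lists were called, 1 higher and 1 lower, and the lower one was myelin. The insulin and IGF list, then without Igf2, was not called there, nor were the precursor and dentate granule neuron lists.

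Dentate granule neuron markers had 2 of 7 lower (3 adjusted over the list alone), the guidance receptor gene Sema5a at -1.57 ± 0.45 and the synaptic C1q-like gene C1ql2 at -0.72 ± 0.26 (list adjusted p = 0.0422; adjusted p = 0.174 with an estimated correlation). Cytosolic ribosomal protein genes had 6 of 39 higher, also 6 adjusted over the list alone, among them Rpl13, Rpl37, Rpl19 and Rps3 at 0.26 to 0.38. Their list was called upward (adjusted p = 0.0215; adjusted p = 0.174 with an estimated correlation). Its median of 0.12 became -0.00379 with library totals, so the sign of that median rests on the scaling. Library totals moved the median log2 fold change of all genes by -0.12. Camera compares the list with the other genes, so a shift common to all genes does not bear on its call. Rpl37, Rpl19 and Rps3 overlap other genes, and all 3 lost their calls without Ctrl 1 or Model 1 and with library totals (adjusted p up to 0.185).

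Leaving out a single library ended several of these calls. Sema5a lost its call without Ctrl 2, and C1ql2 without any library except ChryM 2 or ChryM 3 (adjusted p up to 0.152). Sox10 lost its call without Ctrl 2, Ctrl 3, Model 2 or Model 3, and Cspg4, which overlaps Cimap1c, without Ctrl 2, Ctrl 3, Model 1 or Model 2 (adjusted p up to 0.196 and 0.208). With 1 surrogate variable Olig1, Sox10, Cspg4, Sema5a, C1ql2, Rpl13, Rpl37 and Rps3 were not called (adjusted p = 0.188 to 0.595). On log2(FPKM + 1) Rpl13, Rpl37, Rpl19 and Rps3 were not (adjusted p = 0.0943, 0.0527, 0.202 and 0.121), nor Sox10, Cspg4, C1ql2 and Rps3 without a count filter (adjusted p = 0.0647, 0.0685, 0.115 and 0.0514). The insulin and IGF list lost its call without Ctrl 1, Ctrl 3 or Model 3 (adjusted p = 0.0613, 0.128 and 0.0510), and the ribosomal list without Ctrl 3 (0.0658). The dentate list was lost without Ctrl 1, Ctrl 2, Ctrl 3, Model 2 or ChryM 1, and the precursor list without any of the libraries except ChryM 3 (adjusted p up to 0.0876 and 0.221). Without Ctrl 3 there were 2 lists called in place of 6, and without Ctrl 1 there were 3. The other 30 tested lists had adjusted p of 0.0681 to 0.869, and in 10 of those the median, mean and test differed in sign. Among them were nuclear genes of oxidative phosphorylation (adjusted p = 0.0681), glucocorticoid receptor targets (adjusted p = 0.869), immediate early genes (adjusted p = 0.753) and NRF2 and antioxidant genes (adjusted p = 0.805).

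**Figure D2:**
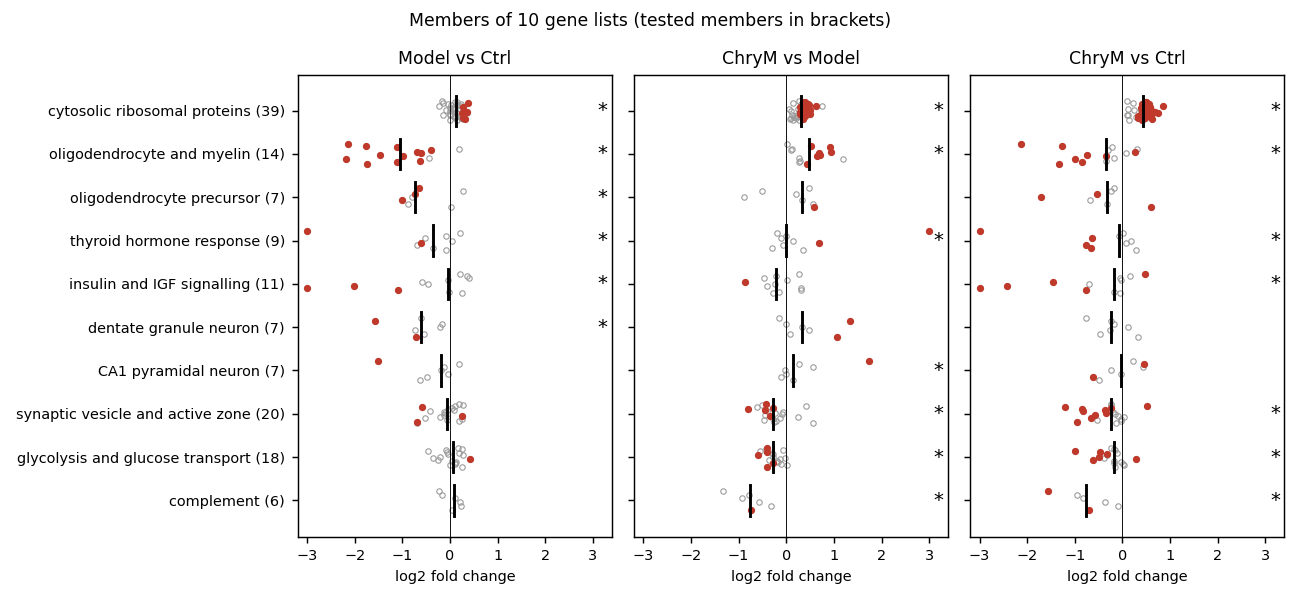
Log2 fold changes of the tested members of 10 gene lists in the 3 comparisons, with values beyond -3 or 3 drawn at those limits; filled red points are called members, open points are not, black bars are medians, and an asterisk marks a list with a camera adjusted p under 0.05 at the preset correlation. Myelin genes lay mostly below 0 in Model vs Ctrl and above 0 in ChryM vs Model, and ribosomal protein genes lay above 0 in both comparisons of ChryM.

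The second comparison, ChryM against Model, addresses what differs in hippocampal RNA with chrysophanol. Myelin transcripts were among the genes with the smallest p. Mobp (ENSRNOG00000018700), a myelin-associated basic protein gene, rose from 4080 ± 572 to 7850 ± 630 CPM, a log2 fold change of 0.94 ± 0.07 (adjusted p = 9.72e-26). Mbp (ENSRNOG00000016516), the myelin basic protein gene, rose from 4310 ± 78.3 to 6950 ± 115 CPM, by 0.69 ± 0.07 (adjusted p = 7.60e-17). Of 14 myelin genes 7 rose and 0 fell (8 adjusted over the list alone), with a median of 0.47, and a further member was Mag at 0.65 ± 0.12. The list was called upward (adjusted p = 7.62e-12; adjusted p = 0.0121 with an estimated correlation). Wfs1 (ENSRNOG00000005108), an endoplasmic reticulum gene that marks CA1 pyramidal neurons, rose from 25.7 ± 4.17 to 86.7 ± 12.7 CPM, by 1.73 ± 0.23 (adjusted p = 1.48e-11). Ttr rose from 6 to 101 counts, a ratio of 13.7 with a 95% counting interval of 6.06 to 38.1.

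Ribosomal protein genes rose together. Rps19, Rps23, Rpl26 and Rpl5 rose by 0.62 ± 0.10, 0.47 ± 0.08, 0.39 ± 0.09 and 0.42 ± 0.10 on the log2 scale. Of 39 tested members 20 rose and 0 fell (27 adjusted over the list alone), with a median of 0.32 (adjusted p = 2.80e-14; adjusted p = 0.00901 with an estimated correlation). Rps23 overlaps Atp6ap1l, and Rpl5 lost its call without ChryM 1 (adjusted p = 0.0625). With 1 surrogate variable Rpl26 and Rpl5 were not called (adjusted p = 0.407 and 0.187). The median stayed positive with DESeq2 size factors and with library totals, at 0.31 and 0.37. The ferritin heavy chain gene Fth1 (ENSRNOG00000022619), for iron storage, rose from 957 ± 47.4 to 1660 ± 116 CPM, by 0.80 ± 0.07 (adjusted p = 1.83e-19). Slc16a13, a monocarboxylate transporter gene, rose by 1.04 ± 0.09 and Sgf29, a histone-binding protein gene, by 0.96 ± 0.09, but they overlap Slc16a11 and Dppa3l3, and the strand setting of the counting is not given. The largest rises at low counts were Flrt3 (2.12, inside Macrod2), Aurkc (1.56), Robo3 (1.51, overlapping Robo4) and Prex2 (1.49). Aurkc, Robo3 and Prex2 lost their calls with 1 surrogate variable (adjusted p = 0.0743, 0.0883 and 0.481). Robo3 also lost its call without ChryM 3 (0.0654) and Prex2 without ChryM 2 (0.151).

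Of the genes lower in ChryM than in Model, Sncg fell to 13.8 ± 3.70 CPM, a log2 fold change of -2.97 ± 0.27 (adjusted p = 2.45e-25), and Necab1 to 2140 ± 45.0 CPM, at -0.84 ± 0.07 (adjusted p = 6.84e-23). Nefm (ENSRNOG00000013916), which encodes the medium neurofilament chain, fell from 929 ± 58.9 to 518 ± 56.8 CPM, at -0.84 ± 0.08 (adjusted p = 1.76e-18). Pced1b (-1.12, also overlapping a pseudogene), Nnat (-0.99), the neuronatin gene, and Gpr39 (-0.97), a zinc receptor gene, overlap Amigo2, Blcap and Lypd1, so reads of those neighbours may be counted in them. Apold1 (ENSRNOG00000007830), an endothelial early-response gene, fell from 56 to 6 counts (ratio 11.5 with a 95% counting interval of 4.97 to 32.7), and Klf2 (-2.44, overlapping Eps15l1) from 41 to 9. Igsf1 (-2.25), Or5a3 (-1.93) and Syn3 (-1.75, overlapping Fbxo7 and Timp3) completed the largest falls. Or5a3 lost its call with 1 surrogate variable (adjusted p = 0.241). Igsf1 lost it there, on log2(FPKM + 0.1) and without ChryM 2, with adjusted p of 0.0521 to 0.137.

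Synaptic vesicle and active zone genes had 5 of 20 members lower, among them the SNARE genes Snap25 at -0.34 ± 0.07 and Vamp2 at -0.43 ± 0.09, the synapsin gene Syn1 at -0.46 ± 0.12 and the synaptophysin gene Syp at -0.28 ± 0.07. Syn1 overlaps Araf and Timp1, and it lost its call with 1 surrogate variable, at -0.19 (adjusted p = 0.673), and on log2(FPKM + 1) (adjusted p = 0.0736). Syp lost its call in the same settings (adjusted p = 0.324 and 0.112) and without Model 1 or ChryM 2 (adjusted p = 0.0822 and 0.0675). Adjusted over the list alone, 11 were lower and 1 higher, and the list was called downward with a median of -0.28 (adjusted p = 7.12e-05; adjusted p = 0.0333 with an estimated correlation).

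Glycolysis and glucose transport had 5 of 18 lower (7 adjusted over the list alone), including Tpi1, Pkm, Pfkp and Eno2 at -0.28 to -0.59 (list adjusted p = 2.46e-05; adjusted p = 0.0686 with an estimated correlation). Tpi1 overlaps Spsb2, Pfkp lost its call without Model 3 (adjusted p = 0.260) and Eno2 without Model 1, Model 2, ChryM 1 or ChryM 3 (adjusted p up to 0.155). With 1 surrogate variable Tpi1 and Eno2 were not called (adjusted p = 0.0997 and 0.204), with DESeq2 Pfkp and Eno2 were not (0.0740 and 0.0591), and on log2(FPKM + 1) Pkm, Pfkp and Eno2 were not (0.146, 0.110 and 0.195). Eno2 was also lost with library totals and with other count filters (adjusted p = 0.0578 to 0.107). Complement had 1 of 6 lower (3 adjusted over the list alone), C1qa, a microglial initiator of the classical pathway, at -0.75 ± 0.21 (list adjusted p = 0.00710; adjusted p = 0.107 with an estimated correlation). C1qa lost its call without Model 1, ChryM 1 or ChryM 3 (adjusted p = 0.179, 0.128 and 0.0601), with DESeq2 (0.0802), with 1 surrogate variable (0.300) and on log2(FPKM + 1) (0.0826). Summed as CPM of the library total, the 14 complement genes stood at 174 ± 9.82 in Model and 115 ± 16.3 in ChryM, and the 17 microglia and macrophage markers at 158 ± 10.8 and 109 ± 18.3, ratios of 0.665 and 0.692; both lists hold C1qa, and the sums were not tested. The thyroid list was called upward through Mbp and Ttr (2 of 9 higher; adjusted over the list alone, 2 higher and 1 lower; adjusted p = 0.00800; adjusted p = 0.213 with an estimated correlation). Without genes shared with other lists it was not called and its sign turned (adjusted p = 0.880). CA1 markers, with Wfs1 the 1 called member of 7 (2 adjusted over the list alone), had a list adjusted p of 0.0423 (adjusted p = 0.213 with an estimated correlation), which was lost without Ctrl 3, Model 1, ChryM 2 or ChryM 3. The other 29 lists had adjusted p of 0.0521 to 0.863, with signs of median, mean and test that differed in 3.

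In all, 585 genes changed between ChryM and Model, 273 higher and 312 lower, and 1368 had an unadjusted p under 0.05. At least 2-fold were 42 of the rises and 46 of the falls. With library totals the split was 373 higher and 252 lower, and on log2(FPKM + 1) it was 216 and 144. It was 106 and 156 with DESeq2, 113 and 109 with 1 surrogate variable, 134 and 141 with a fold of at least 1.5, and 37 and 37 among the 1087 tested genes over 5 kb from another gene.

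A set of 173 genes changed between Model and Ctrl and then in the opposite direction between ChryM and Model: 119 rose and then fell, and 54 fell and then rose. Those with the smallest larger p included Sncg, Necab1, Mobp, Ttr, Pced1b, Mbp, Nnat, Cibar2, Wfs1, Gpr39 and Syn3. Mbp stood at 6600 ± 140, 4310 ± 78.3 and 6950 ± 115 CPM in Ctrl, Model and ChryM, and Wfs1 at 74.9 ± 16.9, 25.7 ± 4.17 and 86.7 ± 12.7. Ttr stayed far below Ctrl in ChryM, at 42.7 ± 4.09 CPM. Only 32 genes changed in the same direction in both comparisons. Because both comparisons hold the same Model libraries, chance alone opposes them. Simulated libraries with no difference between groups gave 0.1 opposed calls on average and 2 at most in 100 data sets. Independent lists of the observed sizes would share 36.7, but each figure leaves out what the other holds, so neither excess measures a shared effect. Over all genes, measures of opposition went apart. The covariance of the 2 fold changes was -0.0803, against a simulated mean of -0.0420 (range -0.0460 to -0.0387), a difference of -0.0383. The correlation was -0.423 against a simulated mean of -0.55, and 60.1% of genes had opposite signs against a simulated 68.3%. Both values are less opposed than in the simulation, which holds no group differences. A change in Ctrl or ChryM alone would weaken both measures, so they do not show less opposition. Genes are not independent replicates. The Model libraries were also split in all 6 ways, with 1 part set against Ctrl and the other against ChryM. No library is then shared, but 1 part holds a single library. The correlation in these splits was -0.179 to -0.099, against simulated means of -0.00355 to 0.00298. The covariance was then -0.0481 to -0.0273 with a mean of -0.0382, against -0.00656 to 0.00707 in 90 simulated data sets, with 50.1% to 53.1% of genes opposite in sign (simulated means 49.8% to 50.2%) and 55 to 79 opposed calls (simulated at most 1). A single library also has less power, so the drop from 173 does not measure the sharing, and part of the 173 may come from it. The 173 became 94 with DESeq2, 99 on log2(FPKM + 1), 68 with a fold of at least 1.5 and 54 with 1 surrogate variable. Among the 1087 tested genes over 5 kb from another gene, 17 were opposed and 97 had changed in Model vs Ctrl. The covariance was -0.386 with DESeq2, which was run on all 30562 genes, and -0.581 and -0.443 with other count filters. Those settings include more genes of few counts. The covariance was -0.1425 with 1 surrogate variable and -0.0438 among genes with a mean count of at least 30. The opposed calls were 19.7% of the 879 genes changed in Model; 493 of those 879 were still called in the same direction in ChryM against Ctrl and 374 were not called there.

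**Figure D3:**
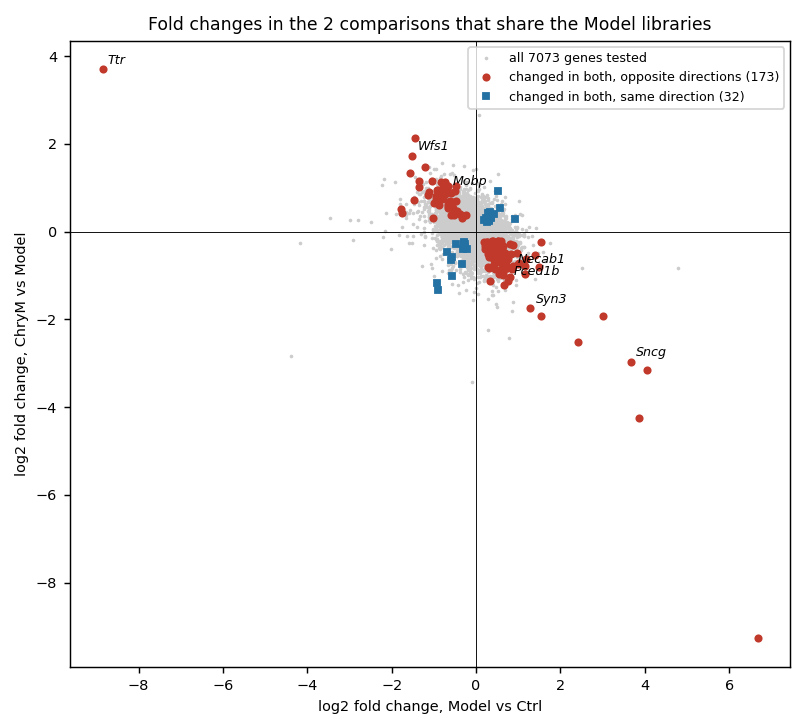
Log2 fold changes of 7073 tested genes in Model vs Ctrl (horizontal) and ChryM vs Model (vertical); red points are the 173 genes called in opposite directions and blue squares the 32 called in the same direction. Ttr, at -8.86 and 3.70, and Sncg, at 3.67 and -2.97, lie far from the other named genes.

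The third comparison, ChryM against Ctrl, shows how far the chrysophanol group lay from the controls; it is the sum of the first 2 and not independent of them. Ttr stayed lower by -5.15 ± 0.15, Enpp2 by -2.27 ± 0.17, Igf2 by -3.17 ± 0.28 and Hba-a1 by -1.72 ± 0.12 on the log2 scale. The genes that rose with the smallest p were Alg3 at 1.00 ± 0.08, Ube3a at 1.21 ± 0.09, Or2b4 at 1.303 ± 0.09, Sgf29 at 1.02 ± 0.09 and Ptpn11 (ENSRNOG00000030124), which encodes the phosphatase SHP2, at 1.46 ± 0.13. Ptpn11 went from 73.2 ± 3.46 CPM in Ctrl through 105 ± 6.71 in Model to 201 ± 12.1 in ChryM. Those genes kept their calls under each alternative fixed beforehand that was run for single genes. None of these alternatives tests whether the reads are those of the named mRNA, and Sgf29 overlaps Dppa3l3. In all, 1329 genes changed, 695 higher and 634 lower, 67 and 142 of them at least 2-fold, and 2093 had an unadjusted p under 0.05. With library totals the split was 520 and 819, with DESeq2 385 and 206, on log2(FPKM + 1) 349 and 450, with a fold of at least 1.5 it was 277 and 424, and among the 1087 tested genes over 5 kb from another gene 48 and 121.

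Ribosomal protein genes lay above Ctrl, with 27 of 39 higher and 0 lower (30 adjusted over the list alone) and a median of 0.44 (adjusted p = 1.07e-18; adjusted p = 0.00423 with an estimated correlation). The other 11 lists called were lower, and none of those kept its call with an estimated correlation. Myelin had 7 lower and 1 higher of 14 (9 and 1 adjusted over the list alone; adjusted p = 1.23e-05; adjusted p = 0.0550 with an estimated correlation). Synaptic vesicle genes had 9 lower and 1 higher of 20 (10 and 1 adjusted over the list alone; adjusted p = 0.000150; adjusted p = 0.0550 with an estimated correlation). Cholesterol synthesis had 6 of 15 lower (8 adjusted over the list alone), including the synthase gene Hmgcs1 at -1.16 ± 0.14, the demethylase gene Cyp51 at -1.12 ± 0.21 and the oxidase gene Msmo1 at -0.92 ± 0.30. Its median was -0.59 (adjusted p = 0.000996; adjusted p = 0.0554 with an estimated correlation). Msmo1 lost its call without Ctrl 2, ChryM 2 or ChryM 3 (adjusted p up to 0.452) and on log2(FPKM + 1) (0.0897).

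Astrocyte markers had 4 of 12 lower, also 4 adjusted over the list alone: the water channel gene Aqp4 at -0.92 ± 0.15, the glutamate transporter gene Slc1a3 at -0.92 ± 0.15, Gfap at -0.36 ± 0.09 and the gap junction gene Gja1 at -0.41 ± 0.13 (list adjusted p = 0.0195; adjusted p = 0.143 with an estimated correlation). Gja1 lost its call without Ctrl 2 or ChryM 2 (adjusted p = 0.0632 and 0.0522), with DESeq2 (0.139) and without a count filter (0.0562). Insulin and IGF signalling had 4 lower and 1 higher of 11, the same adjusted over the list alone (adjusted p = 0.00483; adjusted p = 0.0850 with an estimated correlation). Glycolysis had 5 lower and 1 higher of 18 (7 and 1 adjusted over the list alone; adjusted p = 0.00589; adjusted p = 0.153 with an estimated correlation). Thyroid hormone response had 4 of 9 lower, also 4 adjusted over the list alone (adjusted p = 0.0191; adjusted p = 0.193 with an estimated correlation), and complement 2 of 6, also 2 adjusted over the list alone (adjusted p = 0.0322; adjusted p = 0.153 with an estimated correlation). Neurotrophins and receptors had 3 of 6 lower, also 3 adjusted over the list alone (adjusted p = 0.0322; adjusted p = 0.153 with an estimated correlation). Glutamate receptors and transporters had 7 lower and 1 higher of 18, the same adjusted over the list alone (adjusted p = 0.0322; adjusted p = 0.193 with an estimated correlation). The unfolded protein response had 3 of 13 lower, Canx, Dnajb11 and Hspa5 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.0357; adjusted p = 0.198 with an estimated correlation). Dnajb11 and Hspa5 were each lost in 9 settings, among them DESeq2 (adjusted p = 0.213 and 0.237) and log2(FPKM + 1) (0.0905 and 0.118).

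In place of the 6, 7 and 12 lists called in the 3 comparisons, a filter of at least 1 CPM in 3 libraries gave 15, 16 and 19. Members of 1 list alone gave 2, 6 and 5. Calls by fry, which does not compare a list with the other genes, were 17, 19 and 17. Single libraries decided some of these 12 calls, and without Ctrl 3 there were 7. The complement list was lost without Ctrl 3 or ChryM 1, the thyroid list without Ctrl 3 or ChryM 3 and the astrocyte list without ChryM 2. The glutamate list was lost without Ctrl 3, ChryM 1 or ChryM 2, and the unfolded protein response without Ctrl 1, Ctrl 3, ChryM 2 or ChryM 3. The neurotrophin list was lost without any of Ctrl 1 to 3, Model 1, Model 3, ChryM 2 or ChryM 3. The adjusted p without such a library reached 0.141 for the thyroid list and 0.116 for the unfolded protein response. The other 24 lists had adjusted p of 0.0826 to 0.984, with signs of median, mean and test that differed in 5.

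Summed levels of cell and tissue markers, as CPM of the library total, gave a view of lists with too few tested members. The 19 choroid plexus markers summed to 1830 ± 36.6 CPM in Ctrl, 52.9 ± 5.35 in Model and 102 ± 6.77 in ChryM, and the 17 markers of fibroblasts and meninges to 386 ± 3.90, 119 ± 14.6 and 185 ± 30.1. Red blood cell markers summed to 577 ± 23.3, 273 ± 14.6 and 298 ± 33.5 CPM. Mural cell markers stood at 131 ± 6.10, 72.8 ± 19.4 and 79.1 ± 10.4 CPM, endothelial markers at 110 ± 14.4, 90.4 ± 10.3 and 60 ± 2.36, and ependymal markers at 60.5 ± 9.77, 47.2 ± 7.47 and 34.7 ± 8.83. Microglia and macrophage markers were 160 ± 10.4, 158 ± 10.8 and 109 ± 18.3 CPM. Markers of hypothalamus and midbrain, which include Nnat, were 858 ± 16.5, 1130 ± 56.3 and 749 ± 14.9 CPM. Thalamus markers were 84.2 ± 9.70, 96.3 ± 6.85 and 63.4 ± 10.3 CPM, striatum markers 146 ± 13.9, 131 ± 0.546 and 140 ± 9.66, and neutrophil and leukocyte markers 8.50 ± 1.55, 10.2 ± 1.01 and 10.7 ± 6.76. These sums were not tested.

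Immune lists were also near the limit of depth. Pro-inflammatory cytokines and chemokines summed to 58.1 ± 12.9, 30.1 ± 2.78 and 24.6 ± 3.93 CPM in Ctrl, Model and ChryM, and inflammasome and purinergic receptor genes to 15.9 ± 1.72, 17.8 ± 1.42 and 20.2 ± 5.56. The cytokine and chemokine list held 137, 62 and 60 counts. Its 2 members with enough counts to be tested were the adhesion molecule genes Vcam1 and Icam1, while Il1b, Tnf and Il6 had 0 counts. Neither tested member was called in Model vs Ctrl or ChryM vs Model, and 1 was lower in ChryM vs Ctrl. Interferon-stimulated genes summed to 169 ± 20.4, 110 ± 13.7 and 92.7 ± 8.70 CPM. MHC class I genes summed to 222 ± 10.2, 189 ± 11.3 and 159 ± 17.3, and MHC class II genes to 40.1 ± 8.22, 27.4 ± 3.61 and 24.6 ± 3.69. Of 4 interferon genes tested, 1 was lower in Model vs Ctrl, 0 in ChryM vs Model and 2 in ChryM vs Ctrl. Of 2 MHC class I genes tested, 0, 1 and 1 were lower in those comparisons. The 1 tested MHC class II gene was lower in Model and in ChryM than in Ctrl, and not called in ChryM vs Model. None of these genes was called higher. The NF-kB list, at 13900 ± 259, 17000 ± 593 and 15100 ± 438 CPM, was almost wholly Nfkbie (ENSRNOG00000019907), an inhibitor of NF-kB, whose count rose by 0.39 ± 0.07 in Model (adjusted p = 2.86e-06; 0.0531 with 1 surrogate variable). Its level of 13900 CPM of the library total in Ctrl stands against 746 for Actb, and the strand setting of the counting is not given, so its reads may not be those of Nfkbie mRNA. It fell by 0.22 ± 0.07 between Model and ChryM (adjusted p = 0.0256), a call lost with other count filters, with 1 surrogate variable and without Model 1, Model 2, ChryM 1 or ChryM 2 (adjusted p = 0.0808 to 0.636).

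Of the panel of 32 genes fixed before the data were examined, 15 had enough counts to be tested, and Il1b, Tnf, Il6, Slc6a4 and Slc2a4 had 0 counts in all 9 libraries, so no difference in them was detectable at this depth. Ntrk2, the BDNF receptor gene, rose by 0.57 ± 0.16 in Model (adjusted p = 0.00712), a call lost without Model 1 (adjusted p = 0.0982), with 1 surrogate variable (0.270) and on log2(FPKM + 1) (0.219). App, the amyloid precursor gene, went from 1180 ± 35.3 to 980.0 ± 75.5 CPM in Model and 764 ± 38.7 in ChryM, with log2 fold changes of -0.27 ± 0.07 (adjusted p = 0.00564; 0.105 without Model 2 and 0.365 with 1 surrogate variable) and then -0.36 ± 0.08 (adjusted p = 0.000241). Apoe, the main lipid carrier gene of astrocytes, rose from 4240 ± 112 to 5700 ± 186 CPM in Model, by 0.43 ± 0.07 (adjusted p = 1.90e-07), and stood at 5630 ± 73.3 in ChryM. Arc, an activity-regulated gene of synapses, rose by 1.07 ± 0.29 between Model and ChryM (adjusted p = 0.00440; 0.273 with 1 surrogate variable). Gfap, the astrocyte filament gene, fell by 0.28 ± 0.09 there (adjusted p = 0.0278), a call lost without Model 2, Model 3 or any of the ChryM libraries (adjusted p up to 0.166), with library totals (0.0725), DESeq2 (0.0915) and other count filters (0.0995 and 0.123) and on log2(FPKM + 1) (0.288). Nr3c1, the glucocorticoid receptor gene, lay below Ctrl in ChryM by -0.73 ± 0.27 (adjusted p = 0.0410), a call lost without any 1 of the Ctrl or ChryM libraries (adjusted p up to 0.221), with DESeq2 (0.244) and other count filters (0.113 and 0.0965) and on log2(FPKM + 1) (0.0923). Bdnf, Mapt, Aif1, Fkbp5, Sgk1, Irs2 and Slc2a1 were tested and not called in any comparison.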

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

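Alternatives were fixed before the data were examined, except the last 4 named here, which were chosen after results were seen. Counts of changed genes are given for Model vs Ctrl, ChryM vs Model, ChryM vs Ctrl and opposed genes, and the cause was not tested unless given. They were 440, 262, 591 and 94 with the DESeq2 Wald test (covariance -0.386), 440, 275, 701 and 68 with a fold of at least 1.5, which by construction calls fewer, 557, 360, 799 and 99 on log2(FPKM + 1) (covariance -0.0571), and 509, 349, 762 and 99 on log2(FPKM + 0.1). With 1 surrogate variable they were 272, 222, 1294 and 54 (covariance -0.1425), and Mt-nd5 turned to -0.0657 in Model vs Ctrl. The large falls, from 879 and 585, were in the comparisons that hold Model, while ChryM vs Ctrl stayed near its 1329. Whether the variable follows the Model group was not examined, so a call lost with it may reflect that adjustment or a weak call. The covariance was -0.581 without a count filter and -0.443 with a filter of at least 1 CPM in 3 libraries. Both test more genes of few counts. DESeq2 too was run on all 30562 genes, so its values do not separate the tool from the set of genes. Changed lists were 1, 3 and 1 with an estimated correlation, 17, 19 and 17 with fry, 15, 16 and 19 with the CPM filter, and 2, 6 and 5 with members of 1 list alone. Extracellular matrix genes turned direction in Model vs Ctrl under the CPM filter and were called there (adjusted p = 0.0344) and thyroid hormone genes in ChryM vs Model with members of 1 list alone (adjusted p = 0.880). Leaving out 1 library gave 615 to 886, 390 to 619, 971 to 1349 and 118 to 188 genes, 2 to 6, 6 to 9 and 7 to 12 lists, and a covariance of -0.126 to -0.0848. A replicate block on the library numbers gave 855, 586, 1317 and 169 genes, 6, 7 and 12 lists, and a covariance of -0.0800; C1ql2 lost its call in Model vs Ctrl (adjusted p = 0.0574; 0.0506 to 0.595 over all settings that lost it). Correlations of same-numbered libraries were -0.0304 to 0.0421 and 2 of 9 libraries correlated best with their own number, so the numbers do not pair. Of 19, 22 and 10 named genes, 17, 17 and 10 kept their call under all alternatives fixed beforehand and run for single genes. With list members, 41 of 85, 29 of 70 and 61 of 101 did. Of the lists, 1 of 6, 3 of 7 and 1 of 12 kept their call under all alternatives run for lists. Of the additions, genes over 5 kb from another gene gave 97, 74, 169 and 17 (fewer genes tested; covariance -0.1086), a mean count of at least 30 gave 699, 548, 1058 and 159 (covariance -0.0438), removing marker genes gave 846, 572 and 1309, and splitting the Model libraries 1 and 2 gave a mean covariance of -0.0382, which by construction lacks the part from sharing them. In data simulated at the observed depth, planted folds under 2 were recovered least, and no other depth was tried.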

Other observations

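The tests in this part were chosen after results were seen, except the exchange of libraries between groups. An unnamed gene, ENSRNOG00000064836, chosen after its values were seen, had 2, 200 and 0 counts in Ctrl, Model and ChryM. Zfp57, which overlaps the myelin gene Mog, stood at 22.7 ± 2.23, 20.9 ± 1.39 and 25.7 ± 1.82 times the level of Mog.

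Gene abundances were unlike brain tissue: Ppp3r1 stood at 28300 ± 1530 CPM of the library total in Ctrl, against 183 ± 14.8 for Camk2a and 746 ± 5.67 for Actb. Reads counted on the strand opposite to transcription were tested first through overlaps, which were 1.14 times as frequent among the 100 highest genes (53.0% against 46.4%), under the bound of 1.5, so that test went against the idea, although overlaps on the same strand dilute it. A later test, chosen after that outcome, used Mt-nd6, the mitochondrial mRNA of the other strand, which was at least 3.56 times the median of the other mitochondrial mRNAs; it goes with opposite-strand counting for those mRNAs, and 3.56 argues against counting without regard to strand. Low depth alone passed its 1st test, with textbook-abundant mRNAs at a median percentile of 96.9, and failed a 2nd and a 3rd test chosen after that outcome, with 4 such mRNAs among the 100 highest nuclear genes and a ratio of Mt-nd6 to Mt-co1 of at least 1.26. As the supporting tests replaced ones that had gone the other way, opposite-strand counting stays an open hypothesis, and no biological explanation was tested.

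Replicate libraries of a group lay close to counting noise. The median CV within groups beyond counting was 3.66% in 210 genes with at least 500 counts, which argues against low depth hiding differences between animals. At most 3 genes were at least 4-fold apart in a pair of libraries of 1 group, against 7 to 24 between groups. Whether there was 1 RNA source per group, such as a pool or a single animal, stays open. If so, differences between groups could be differences between animals or dissections.

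Markers of choroid plexus, meninges and myelin were lower in Model. Of the choroid plexus markers other than Ttr and Enpp2 with at least 10 counts, 100% (11 of 11) were lower in both Model and ChryM than in Ctrl, which fits less choroid plexus tissue in those libraries, by dissection or by biology. The sizes were unlike. Markers other than Ttr and Enpp2 summed to 111 ± 6.46, 20 ± 2.05 and 23.8 ± 5.16 CPM in Ctrl, Model and ChryM, a fall of 5.16 times in Model (95% counting interval 3.70 to 7.36), but 30 of their 41 Model counts were Trpm3, which had 48 in Ctrl. The other 16 fell 15.7 times (8.58 to 31.9), from 211 to 11 counts, against 488 times (224 to 1330) for Ttr, which rose 13.7 times in ChryM vs Model. With so few counts left, and with no test of whether other cells make these markers, it stays open whether a loss of tissue was the only cause. A lower share of myelinated tissue alone would move the 14 myelin genes alike only if other cells made none of them. Each count would also have to be of the gene's own mRNA, and neither condition was tested. The log2 fold changes of these genes spread with a chi-square per degree of freedom of 21.7 in Model vs Ctrl. It was 5.07 in ChryM vs Model and 33.4 in ChryM vs Ctrl. The genes thus did not move alike, but this does not decide whether a lower share of myelinated tissue was the only cause. An effect of the protocol on these genes was not excluded.

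Libraries were exchanged between the groups of each comparison in all 10 ways, and between the 3 groups in 100 splits, the real one and others drawn at random. With 10 splits, splits are too few for a share under 0.05. The real groups gave 879, 585 and 1329 changed genes against at most 0, 1 and 1 in other splits, and 6, 7 and 12 lists against at most 2, 4 and 4; in each, only 1 of 10, the real split, was as large. For the 173 opposed genes, 3 of 100 splits were as large; the others, 267 and 493, both set the 3 Ctrl libraries between the other groups, so they reflect the structure of the groups. The 493 is the count of genes changed the same way in Model and ChryM against Ctrl, given in the report, and so no new outcome. For the covariance of -0.0803, 14 of 100 were as negative. The lowest, -0.157, came from the split with 267 opposed genes. Drawn splits mix libraries of groups that differ, so this share does not measure chance, and chance was not excluded.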
